A study of Mus musculus with 6 samples.

How the data were processed

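Libraries were made from total RNA of 6 samples by the TruSeq small RNA protocol with enrichment of small RNA, per the labels' protocols. RNA was extracted with a silica column kit (RNeasy Plus Mini). Column kits of this type recover short RNAs less well than long ones in their standard form, and the labels do not say which form was used. Bowtie 1.0.1, Bowtie2 and the build mm10 are named in the submitters' processing notes, without the step or the table each was used for. How reads matching several features were counted is not given in the sources used here.

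The authors deposited 2 tables for the whole series. Each has a column of feature names and 6 columns of whole numbers, which the file names call raw counts. The 12 columns of per-sample values have code names that match none of the sample labels. Their numeric order was not taken as a map to the samples, and no value from them is reported. When the content and unit of the tables were examined, column totals and the most abundant rows were seen. Some abundant RNAcentral-style identifiers had values close to those of abundant miRNAs such as miR-22-3p, and many rows had equal values, so that table may hold small RNAs of several types with reads counted on each matching entry. This was not tested. Because no column was matched to a sample, the planned tests of knockdown against control were not run. They were a quasi-likelihood test per mature miRNA and per tRNA feature, tests of sums per anticodon, tests of fixed lists, and a ratio of totals. No depth per sample and no precision is given.

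From the name columns, features were counted by type with Python 3.11.15. Mature miRNA names were split into a stem and an arm. A stem was matched to a GENCODE M21 miRNA gene by its symbol, with any copy number allowed, and 1841 of 1964 names matched. Members of the fixed lists had a match for 399 of 423 names. A host gene is a gene of another type that contains the precursor gene on the same strand. An exon is called where an annotated exon of any transcript of the host gene overlaps the precursor. The 34 lists of miRNAs and tRNAs were written before the data were examined, 33 of them for miRNAs. The rule for named genes fixed at that time chose miRNAs by test results and by mean level over all libraries. No test was run. The part by mean level, which needs no match of columns to samples, was not applied. The rule therefore named none. The genes named here were chosen afterwards, from the lists and the annotation. By then the most abundant rows had been seen, miR-22-3p among them, and no difference between groups had been computed.

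Beyond the lists described in the results, the list for the cluster of Mir106a had 8 mature names. It left out miR-19b-2-5p and miR-92a-2-5p, which were counted in the list for the cluster of Mir17. The gene Mir19b-2 lies between Mir363 and Mir20b of the Mir106a cluster. For other lists, the numbers of mature names were 6 for the cluster of Mir183, 4 for that of Mir221 and 11 for the clusters of Mir23a and Mir23b. They were 15 for the group of Mir15a and Mir16, 3 for the miR-29 family, 5 for the miR-30 family and 11 for the miR-34 and miR-449 families. They were 4 for the miR-181 family, 7 for the group of miR-99 and miR-10, 3 for the miR-148 family and 28 for the pluripotency clusters. Lists for other tissues had 2 names for endothelium, 15 for muscle, 21 for neural cells, 2 for liver and 7 for neuroendocrine cells, and the hypoxia list had 2. Lists by regulator or target had 9 names for activation by MYC, 27 for repression by MYC, 11 for the androgen receptor and 14 for Pten.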

Results

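The series profiled small RNAs in BM67 cells, a mouse prostate cancer line that lacks the tumour suppressor PTEN and was derived from a prostate-specific Pten knockout model. Cells carried a stable lentiviral shRNA against estrogen receptor alpha, the nuclear hormone receptor encoded by Esr1, or a non-silencing shRNA. The labels describe 6 samples, 3 of the control line and 3 of the knockdown line. RNA was extracted in triplicate from each stable line, so the samples of a group are extractions of 1 line as far as the labels say, and any test between the groups would measure the spread between extractions. The question the design poses is which mature miRNAs and tRNA-derived RNAs differ in level between knockdown and control cells.

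That comparison was not made. The series has 2 tables, 1 for mature miRNAs and 1 named for tRNAs, and each holds 6 columns of per-sample values. The names of these columns are codes that match no sample title, description or characteristic. The order of the columns was not used in place of a match, so no column was given to a sample or to a group. No level, depth per sample, fold change or p-value is therefore given for either group. The knockdown itself was not checked either, since Esr1 mRNA was not measured by small RNA sequencing. What follows uses the names only, and describes which RNAs were listed and where their genes lie. A listed name need not have had reads in any sample. Whether it had could be read without a match of columns to samples, but this was not counted.

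The miRNA table listed 1964 different mature mouse miRNAs. Of these names, 818 ended in 5p, the arm from the 5′ side of the hairpin, and 829 ended in 3p. A further 317 names gave no arm. Both arms were listed for 769 stems, a stem being the name without its arm. A precursor gene with the matching symbol was found in GENCODE M21 for 1841 of the 1964 names (93.7%). GENCODE M21 annotates GRCm38, the assembly also called mm10, which is the build the submitters' processing notes name. All coordinates below are on that build and come from the annotation, counted from 1.

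Several groups of miRNAs with known links to the estrogen receptor were listed by name. The list of miRNAs reported to target Esr1 had 12 mature names in the table. Among their genes, Mir22 lies on chromosome 11 at positions 75463716 to 75463810 on the plus strand. It lies inside the non-coding gene Mir22hg and the protein-coding gene Tlcd2 and overlaps annotated exons of both. Mir221 lies on chromosome X at 19146294 to 19146388 and Mir222 at 19146893 to 19146971, both on the minus strand and outside any annotated host gene on that strand. The list of miRNAs reported to be higher in estrogen receptor positive breast tumours had 11 names.

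Names of epithelial and stromal markers were listed as well, which does not show that these miRNAs were present in the cells. The miR-200 family, which restrains the transition of epithelial cells to a mesenchymal state, had 10 names. Its genes fall into a pair of clusters. Mir200b, Mir200a and Mir429 lie on the minus strand of chromosome 4 between 156053905 and 156055750, inside the protein-coding gene Ttll10. All of them overlap its introns only. They also lie inside the non-coding gene Gm13648, Mir200b and Mir200a in its introns and Mir429 overlapping an exon. Mir200c and Mir141 lie on the minus strand of chromosome 6 between 124717914 and 124718390, within introns of Gm15884. The list of stromal miRNAs had 10 names, the list of basal epithelial miRNAs 6 and the list of blood miRNAs 13.

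The let-7 family, a group of miRNAs that rises with differentiation, had 9 names for its 5p arms, and their genes lay on 7 chromosomes. Mirlet7a-1, Mirlet7f-1 and Mirlet7d lie together on the minus strand of chromosome 13 between 48536012 and 48538272. They lie inside the gene of the long non-coding RNA 6720427I07Rik and overlap its annotated exons. Clusters activated by the transcription factor MYC were listed with both arms. The list for the cluster of Mir17 had 14 names. Among them, miR-19b-2-5p and miR-92a-2-5p are named for other gene copies. For miR-19b this copy is Mir19b-2 on chromosome X, between Mir363 and Mir20b of the Mir106a cluster. The 4 matched genes of the Mir17 cluster on chromosome 14 are Mir17, Mir19a, Mir20a and Mir19b-1. They span 115043671 to 115044391 on the plus strand, lie inside Mir17hg and overlap its annotated exons. No gene was matched by symbol for miR-18a or miR-92a, so the span does not take their genes into account. The cluster of Mir106b, Mir93 and Mir25 had 6 names and lies on the minus strand of chromosome 5 between 138165321 and 138165818, inside Mcm7, which encodes a subunit of the replicative helicase. Mir106b lies in an intron of Mcm7, and Mir93 and Mir25 overlap an exon of some annotated transcript. Exons of all transcripts were pooled, so Mir93 and Mir25 may lie in introns of other transcripts.

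The largest of the lists were a pair named for imprinted clusters. The Dlk1-Dio3 cluster had 108 mature names, and its 51 matched genes on the plus strand of chromosome 12 span 109563692 to 109747960. The list for the Sfmbt2 cluster had 79 mature names. Of its matched genes, 70 lie on the plus strand of chromosome 2 between 10466663 and 10518279, in introns of Sfmbt2. The list goes by name family, and its other matched genes lie outside the cluster, on chromosomes 3, 5, 9, 10, 11 and 13. Many miRNAs of this cluster are near-identical copies, so counts per mature name depend on how shared reads were assigned, which is not given in the sources used here.

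The table named for tRNAs listed 179920 features, of which 170093 (94.5%) were RNAcentral-style identifiers with the mouse taxon number and no gene name, whose RNA type was not looked up. These are numbers of features, not of tRNAs, since the identifiers may include other RNAs and entries that share reads. The other 9827 features had names that gave a tRNA class, 8818 of them with an anticodon and 1009 with a placeholder in its stead. Of these, 8403 (85.5%) were called pseudogenes and 171 had an undetermined class, which left 1253 names with an amino acid or suppressor class. How many of the 1253 names stand for functional tRNA genes was not checked. Serine accounted for 558 of the 1253 names, and 500 of them had the anticodon GCT. Alanine followed with 190 names, of which 140 had the anticodon AGC, and asparagine with 73. The 5636 names that gave a chromosome named chromosomes 10 to 14, with 1356, 2191, 1022, 1061 and 6 names in that order.

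A list of tRNAs whose 5′ fragments depend on sex hormones in breast and prostate cancer cells was fixed before the data were examined. It holds aspartate GTC, histidine GTG and lysine CTT. Among the 1253 names with an amino acid or suppressor class, 11 were aspartate GTC and 22 were lysine CTT. None was histidine GTG, and none of the 1253 gave histidine with any other anticodon. The names that gave a chromosome named chromosomes 10 to 14 only, and just 6 of them named chromosome 14. The lack of histidine is a property of the names listed, not of the cells. The counts by anticodon cover the 1253 names only. Names called pseudogene or undetermined, and the RNAcentral-style identifiers, were not counted.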

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

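No paired analysis was possible because no column of values was matched to a sample, so the replicate numbers of the labels could not be tied to columns. The tests set out before the data were examined were not run for the same reason, nor were their 30 variations in normalization, low-count filter, test, replicate block, left-out libraries and merged copies. The match of mature names to precursor genes was varied after the tables had been seen. It gave 1841 names with any copy number allowed, 1773 where the symbol had to equal the name, and 1841 with the GENCODE basic annotation.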
